A study of Homo sapiens with 12 samples.

How the data were processed

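RNA was measured by sequencing in 12 libraries of Raji cells, 3 for each combination of GFP gate (high or low) and treatment (DMSO or FX1) at 24 h. Total RNA was depleted of ribosomal RNA before library preparation with a KAPA RNA HyperPrep kit, per the labels' protocols. Reads were checked with FastQC, aligned with STAR to hg38 and assigned to genes with featureCounts of the Subread package, and R 4.2.1 was used, per the submitters' processing notes. The deposited values are raw counts per gene, with exons combined, per the file headers. Versions of STAR and featureCounts, the annotation release and the strand setting were not stated, so overlapping and antisense genes, and genes with near-identical copies, are uncertain.

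The table held 60710 lines, of which 3 were left out because they formed a single broken gene record (ANK2). Of the 60707 genes used, 60506 (99.7%) had a symbol and 58439 (96.3%) a gene type in the reference annotation, and 0 count columns lacked a sample. Total counts per library lay between 20454028 and 42556661. PCR reads without molecular identifiers are not independent molecules.

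Counts were tested with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr, leaving 17859, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation and a term for each group was fitted to all 12 libraries with 8 residual degrees of freedom. The contrasts tested were the FX1 effect in each gate, the GFP-low effect under each treatment and the difference of the FX1 effect between gates, each with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are log2 values with standard errors, and levels are TMM-scaled CPM. The 28 gene lists with 517 entries were tested per contrast with camera (limma 3.58.1), which compares a list with the other genes, at a preset correlation between genes of 0.01 and with an estimated one, adjusted over the 28 lists. Lists covered SWI/SNF subunits, BCL6-repressed genes and corepressors, B-cell states and signalling, antigen presentation, interferon, p53, cell cycle, MYC, stress and metabolic responses, the BCL2 family, immediate early genes, and markers of T and NK, myeloid, and epithelial and stromal cells. Some genes are on several lists, so results of overlapping lists are not independent. NFKBIA, NFKBIE, NFKB2, TNFAIP3, TRAF1, BCL2A1, ICAM1, CD40 and CCL22 are on both the NF-kB and the light-zone list. The BCL6-repressed list shares members too, among them CCL3 with the NF-kB list, IRF4 with the light-zone list and TNFAIP3 with both.

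Lists, contrasts, tests, other settings to be tried and the rule for named genes were set before the data were examined. The rule names, per contrast, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2, no placeholder symbol and non-overlapping group ranges (the last not for the difference of the FX1 effect). It also names SMARCA4, SMARCA2, BCL6 and PRDM1, and up to 4 called members with the lowest p in each list, or up to 2 where none was called. Genes with a larger change but a lower mean level are therefore not named. A few genes that the rule takes are not reported here singly, without replacement, and still count in the tests over all genes and lists.

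Those other settings were DESeq2's size factors in edgeR, DESeq2 1.42.0, no low-count filter, a filter of at least 50 counts in 3 libraries, only the groups compared, the replicate number as a block, leaving out mitochondrial genes and genes above 1% of a library before scaling, the estimated correlation, and leaving out each library in turn. Alternatives chosen after seeing the data were a test against a 1.5-fold floor (glmTreat), replicates summed to 4 libraries with 1 residual degree of freedom, and removal of a trend on GC content and length. The last used a smooth trend per library on the GC content and log2 length of each gene's longest transcript, entered as offsets, for 17557 of the 17859 genes (98.3%).

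The fit was tested on simulated data for 17319 genes with known changes. For FX1 in GFP-low cells, 82.1% of genes changed 1.2-fold, 97.3% of those changed 1.5-fold and 100% of those changed 2-fold were recovered. For GFP-low under FX1 the shares were 83.9%, 100% and 100%, and for the difference of the FX1 effect 67.9%, 93.2% and 98.6%. In the 2 contrasts simulated without change, 0 genes were called, and 0 of 20 random lists passed camera. In the contrasts with known changes, 6, 3 and 10 unchanged genes were called in the same order, 3.09%, 1.55% and 5.38% of the calls, the last above the 5% threshold. The simulation changed 56, 73 and 71 genes at these folds, in GFP-low FX1 only, far fewer than the real contrasts called. Genes were drawn independently, with the spread of these libraries and no GC trend, and the random lists held unchanged genes only. It therefore cannot show how the tests behave with correlated genes, a GC trend or a wider spread between cultures.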

Results

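The series profiled RNA from Raji cells, a human Burkitt lymphoma line of germinal centre B-cell type, in an auxin-inducible degron system for SMARCA4 (BRG1), the catalytic ATPase of the SWI/SNF chromatin remodelling complex. Cells gated as GFP-high or GFP-low had received the vehicle DMSO or FX1, a small-molecule inhibitor of the transcriptional repressor BCL6, and were collected at 24 h. The 4 groups held 3 libraries each, 12 in all, made from ribosomal RNA-depleted total RNA. The design text asks how FX1 acts when SMARCA4 protein is degraded, but the labels give the same genotype for all 12 libraries and do not say how GFP relates to the amount of SMARCA4. The groups are therefore called by their GFP gate and treatment.

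Total gene counts per library lay between 20454028 and 42556661. The first principal component of log2 CPM (counts scaled to the TMM-adjusted library total) held 59.8% of the variance and the next held 14.8%. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Within groups, the variance of counts between pairs of libraries was 1.66 to 1.9 times that of random sampling of reads, and the common biological coefficient of variation was 1.67%. Very small changes therefore passed the test, and fold sizes are given beside the counts of genes. Mitochondrial genes took 7.88% ± 0.0344 of counts in GFP-high DMSO (SD, n = 3), 4.28% ± 0.0428 in GFP-high FX1, 4.76% ± 0.0641 in GFP-low DMSO and 5.09% ± 0.0372 in GFP-low FX1. The signal recognition particle RNA RN7SL1 took 0.174% ± 0.0117, 0.325% ± 0.0227, 0.34% ± 0.0273 and 0.569% ± 0.0193 of counts in the same order, and histone genes 0.615% ± 0.00179, 0.483% ± 0.00261, 0.585% ± 0.00809 and 0.318% ± 0.00132.

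SMARCA4 (ENSG00000127616.20, hg38 chromosome 19, 10960932 to 11079426) RNA was present at 381 ± 3.8 CPM (SD, n = 3) in GFP-high DMSO, 388 ± 2.5 in GFP-high FX1, 395 ± 5 in GFP-low DMSO and 456 ± 4 in GFP-low FX1. A degron removes protein, so these RNA levels do not check the gates. BCL6 (ENSG00000113916.18, chromosome 3, 187721377 to 187745725) RNA stood at 400 ± 1.1, 199 ± 3.6, 339 ± 8.9 and 218 ± 7.5 CPM in the same order. PRDM1, which encodes the plasma cell regulator BLIMP1 and is a known BCL6-repressed gene (ENSG00000057657.17, chromosome 6, 105993463 to 106109939), stood at 19.5 ± 0.7, 80.4 ± 1.6, 38.3 ± 0.53 and 124 ± 1.8 CPM. SMARCA2, the alternative SWI/SNF ATPase, ranged from 71.8 ± 0.8 in GFP-low DMSO to 90.2 ± 1 in GFP-high FX1.

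**Figure D1:**
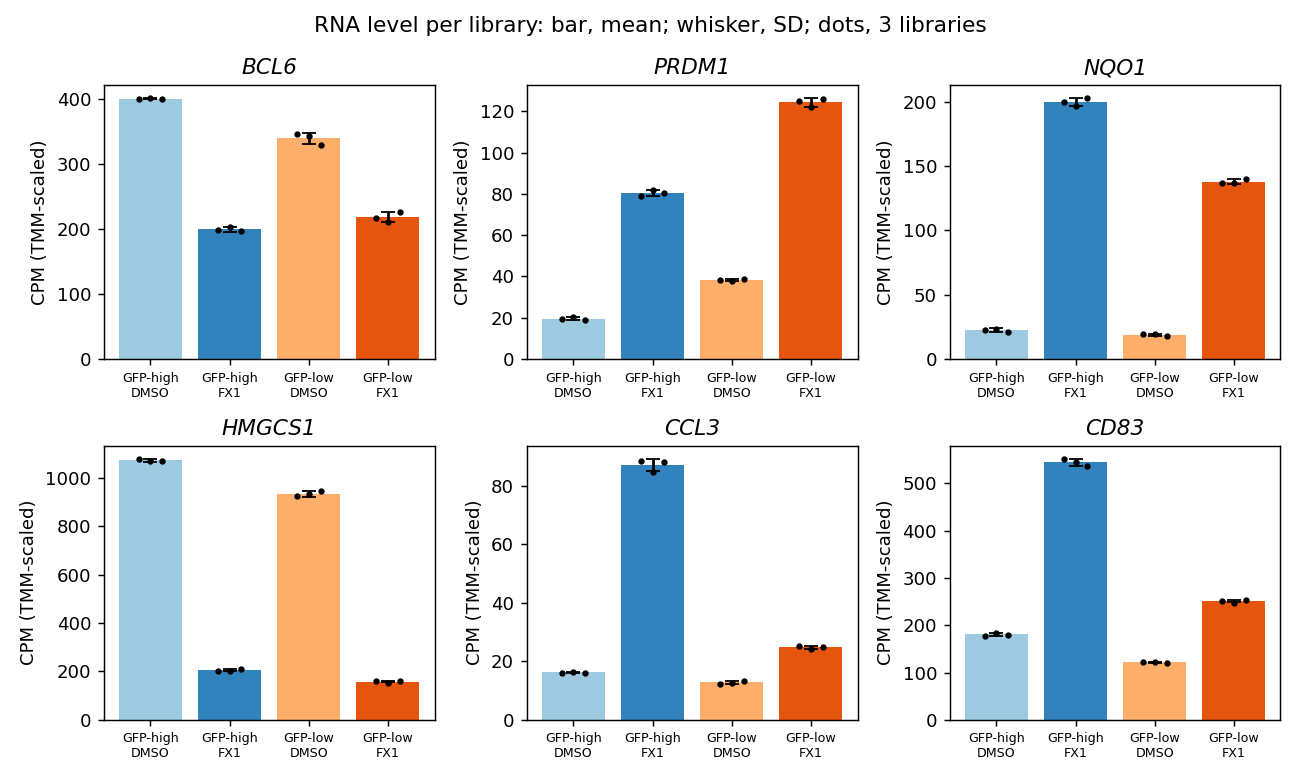
RNA levels of 6 genes in the 4 groups, in TMM-scaled CPM on linear axes, with bars for the mean, whiskers for the SD and dots for the 3 libraries of each group. PRDM1 rose from 19.5 to 80.4 CPM with FX1 in GFP-high cells and from 38.3 to 124 in GFP-low cells, whereas CCL3 rose from 16.2 to 87.2 and from 12.8 to 24.7.

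The comparison of FX1 with DMSO in GFP-high cells asked what the BCL6 inhibitor changed in that gate. All 13 tested NRF2 oxidative stress genes rose (median log2 change 1.29, camera adjusted p = 1.4e-54), among them the quinone reductase NQO1 by 3.15 ± 0.034 (log2, SE), thioredoxin reductase TXNRD1 by 1.87 ± 0.015 and the ferritin chains FTH1 and FTL by 1.8 ± 0.012 and 1.24 ± 0.014. All 19 tested cholesterol synthesis genes fell (median -1.07, camera adjusted p = 6.5e-63), with HMGCS1 at -2.39 ± 0.015. Hypoxia and glycolysis genes fell in 17 of 19 cases (median -1.51, camera adjusted p = 6.5e-63), including lactate dehydrogenase LDHA at -1.52 ± 0.012 and the glycolytic regulator PFKFB4 at -4.03 ± 0.04. All 13 MHC class II genes fell (median -0.89, camera adjusted p = 2.6e-24), with the invariant chain CD74 and HLA-DRA both at -0.89 and SEs of 0.011 and 0.012.

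Lower RNA in the same comparison also covered proliferation and immediate early genes. Of 24 G2/M genes 21 fell and 1 rose (median -0.61, camera adjusted p = 1.3e-20), with MKI67 at -1.03 ± 0.013. Of 23 G1/S genes 20 fell and 2 rose (median -0.58, camera adjusted p = 1.3e-10), with PCNA at -0.79 ± 0.021 and MCM5 among the risers at 0.64 ± 0.017. AP-1 and immediate early genes fell in 13 of 19 cases and rose in 2 (camera adjusted p = 3.3e-10), with FOS at -4.84 ± 0.066, FOSB at -4.8 ± 0.047 and EGR1 at -2.61 ± 0.044, while the phosphatase gene DUSP5 rose by 1.77 ± 0.038. Germinal centre identity genes fell in 12 of 24 cases and rose in 7 (camera adjusted p = 0.0024). RGS13, a regulator of G-protein signalling, changed by -1.22 ± 0.018, BCL6 by -1.01 ± 0.018 and SERPINA9 by 0.96 ± 0.021. The ATF4 response list fell in 17 of 20 cases and rose in 3 (camera adjusted p = 0.0016), with DDIT4 at -2.82 ± 0.025, the risers being the amino acid transporter genes SLC7A5, SLC3A2 and SLC7A11, by 0.95 ± 0.016, 0.78 ± 0.022 and 0.72 ± 0.02. Heat shock genes rose in 10 of 11 cases and fell in 1 (HSPA1B by 1.79 ± 0.034, camera adjusted p = 1e-07). MYC and ribosome biogenesis genes rose in 17 of 22 and fell in 5 (MYC by 0.8 ± 0.017, camera adjusted p = 2e-07), NPM1 falling by 0.56 on the log2 scale. These calls held with an estimated correlation, the largest adjusted p among them being 0.015.

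The list of 22 tested BCL6-repressed genes did not move one way: 10 rose and 11 fell (median -0.06, or 0.07 with a trend on GC content and length removed, camera adjusted p = 0.75). The risers included PRDM1 by 2.04 ± 0.042 and the chemokine gene CCL3 by 2.43 ± 0.048, and the fallers FCER2 by 1.24 and TNFAIP3 by 0.63 on the log2 scale. The B-cell receptor list gave 10 risers and 9 fallers (median -0.02, or 0.06 with that trend removed, camera adjusted p = 0.033 downward, adjusted p = 0.25 with an estimated correlation), with the complement receptor CR2 at -1.48 ± 0.015 and CD22 at -1 ± 0.014. With the trend removed, the camera adjusted p of the B-cell receptor list was 0.0024 at the preset correlation, still downward. For p53 targets, 6 rose and 10 fell (camera adjusted p = 0.031, adjusted p = 0.12 with an estimated correlation), led by CCNG1 at -1.37 ± 0.021 and DDB2 at -2.28 ± 0.041. NF-kB targets gave 14 risers and 5 fallers of 22 (camera adjusted p = 0.21). In the light-zone and CD40 list, 11 rose and 8 fell, with a median of 0.27 and a mean of -0.36 (camera adjusted p = 0.11 upward). CD83, a marker of light-zone cells, rose by 1.59 ± 0.017 and CCL22 fell by 2.51 on the log2 scale. Adjusted over the list alone, counts matched those over all genes for every list except the myeloid markers, where 1 rose and 2 fell.

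By edgeR, 12224 of 17859 tested genes differed in this comparison, 6045 higher and 6179 lower with FX1, and 1052 and 1983 of them by at least 2-fold. Of these 2-fold genes, 503 and 690 were annotated as protein-coding. Counts at 2-fold take the estimated fold of called genes, so imprecise folds enter them. Tested against a floor of 1.5-fold with glmTreat, 3674 of the 17859 genes passed. Among genes with a mean log2 CPM of at least 2, the largest rises were in the organic anion transporter gene SLCO2B1, at 5.2 ± 0.054, CRIM1 at 4.96 ± 0.035 and the peptide receptor gene GRPR at 3.83 ± 0.088. These were followed by NQO1, OSGIN1 (3.14 ± 0.14), the autophagy receptor gene SQSTM1 (2.89 ± 0.018), EID3, CLIP4, LUCAT1 and COL24A1 (2.5 ± 0.06). The largest falls after FOS and FOSB were in LRRC32 (-4.22 ± 0.1), PFKFB4, RNY1, VPREB3 (-3.23 ± 0.096), RNVU1-31, DDIT4, OLMALINC and JPH2 (-2.81 ± 0.12). RNY1 and RNVU1-31 are short noncoding RNAs, and LUCAT1 is uncertain because strand use in counting was not stated. HSPA1A and HSPA1B, or HLA-DRB1 and HLA-DRB5, may share reads, which was not measured. Across 10430 genes the change rose with transcript GC content (Spearman rho 0.293). With the trend on GC content and length removed, 10737 of 12047 calls kept direction and significance, 1212 were lost and 98 turned.

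The comparison of FX1 with DMSO in GFP-low cells gave mostly similar changes, though not in every list. NRF2 genes rose in 13 of 13 cases (median 1.08, camera adjusted p = 7.1e-23), with NQO1 at 2.85 ± 0.036. Cholesterol synthesis genes fell in 18 of 19 (median -1.27, camera adjusted p = 4.4e-36), with HMGCS1 at -2.57 ± 0.016 and INSIG1, a sterol-regulated gene, at -1.56 ± 0.015. MHC class II genes fell in 13 of 13 cases (median -0.65, camera adjusted p = 2.3e-13). Hypoxia and glycolysis genes fell in 15 of 19 (median -1.53, camera adjusted p = 5e-31). G2/M genes fell in 22 of 24 (median -0.66, camera adjusted p = 9.7e-17) and G1/S genes in 20 of 23 against 2 risers (median -0.61, camera adjusted p = 1.3e-09). Germinal centre identity genes fell in 13 of 24 cases and rose in 6 (camera adjusted p = 4.8e-05), led by RGS13 at -2.03 ± 0.021, MYBL1 at -2.01 ± 0.037 and GCSAM at -1.29 ± 0.019. PRDM1 rose by 1.7 ± 0.034 and BCL6 fell by 0.64 on the log2 scale, while IRF4, a regulator of plasma cell fate, changed by -2.28 ± 0.1.

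Other lists in GFP-low cells moved as follows. MYC and ribosome biogenesis genes rose in 18 of 22 cases and fell in 3 (camera adjusted p = 1.1e-07). Heat shock genes rose in 9 of 11 and fell in 1 (camera adjusted p = 0.00072), and the ATF4 list fell in 15 of 20 and rose in 4 (camera adjusted p = 0.0057). AP-1 and immediate early genes fell in 10 of 19 cases and rose in 4 (camera adjusted p = 0.0034), with FOS at -3.61 ± 0.065 and FOSB at -3.41 ± 0.045. The BCL6-repressed list gave 8 risers and 12 fallers (camera adjusted p = 0.22), with TNFAIP3 at -1.05 ± 0.021. The calls given so far for GFP-low cells held with an estimated correlation, the largest adjusted p being 0.034. NF-kB targets gave 13 risers and 8 fallers of 22 (median 0.12, camera adjusted p = 0.46). Light-zone genes gave 9 and 9 of 20 (median 0.03, camera adjusted p = 0.7). B-cell receptor genes gave 8 and 10 of 21 (median 0.02, camera adjusted p = 0.1). With the GC and length trend removed, the NF-kB median was -0.06 (camera adjusted p = 0.0031). The light-zone median was then -0.28 (adjusted p = 0.12) and the B-cell receptor median -0.07 (adjusted p = 3.6e-07). SWI/SNF subunits rose in 18 of 27 cases and fell in 6 (median 0.25, camera adjusted p = 0.021, adjusted p = 0.065 with an estimated correlation). With the GC and length trend removed the median was 0.14 (adjusted p = 0.4). MHC class I genes rose in 7 of 12 and fell in 2 (median 0.11, camera adjusted p = 0.042, adjusted p = 0.13 with an estimated correlation). Without the trend the median was 0.08 (adjusted p = 0.51). Unfolded protein response genes fell in 10 of 16 and rose in 4 (median -0.17, camera adjusted p = 0.042, adjusted p = 0.087 with an estimated correlation). Their median without the trend was -0.12 (adjusted p = 0.079), so most of the fall remained though the call was lost. For p53 targets, 12 of 20 fell and 8 rose (camera adjusted p = 0.042, adjusted p = 0.13 with an estimated correlation), and AHR response genes rose in 3 of 4 (camera adjusted p = 0.021, adjusted p = 0.16 with an estimated correlation). Of 6 T and NK cell markers 5 fell (median -1.26, camera adjusted p = 0.22), with LCK at -1.67 ± 0.11. Of 4 myeloid markers 2 rose and 1 fell (median 0.75, camera adjusted p = 0.6), with ITGAM at 1.42 ± 0.17, CD14 at 2.1 ± 0.54 and CSF1R at -1.1 ± 0.35. CD14 went from only 0.138 to 0.574 CPM and CSF1R from 0.951 to 0.439 CPM, near the floor. COL1A1, 1 of 2 epithelial and stromal markers, rose by 0.39 ± 0.075 but was at -0.05 and not called with the trend removed (camera adjusted p = 0.6 for the list). Adjusted over the list alone, 19 SWI/SNF subunits, 9 B-cell receptor genes and 8 MHC class I genes rose and 3 MHC class I genes fell. All other counts of the lists named here stayed the same except hypoxia and glycolysis, where 1 member rose.

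By edgeR, 12138 genes differed in GFP-low cells, 6011 higher and 6127 lower, with 1144 and 1615 at 2-fold or more and 3606 past the 1.5-fold floor. Protein-coding genes made up 621 and 631 of the 2-fold calls. Among 9996 genes called in both GFP gates, 9421 (94.2%) had the same direction, with 4687 higher in both (2035 from independent lists) and 4734 lower in both (2120). The FX1 effects in the 2 gates, which share no library, correlated across genes with Pearson's r = 0.829 and Spearman's rho = 0.806, genes not being independent replicates. In GFP-low cells the change also followed GC content (rho 0.499), and with the trend removed 9549 of 11964 calls kept direction and significance, 1927 were lost and 488 turned. SMARCA4 RNA, at 0.21 ± 0.015 here, was at -0.23 with the GC and length trend removed.

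**Figure D2:**
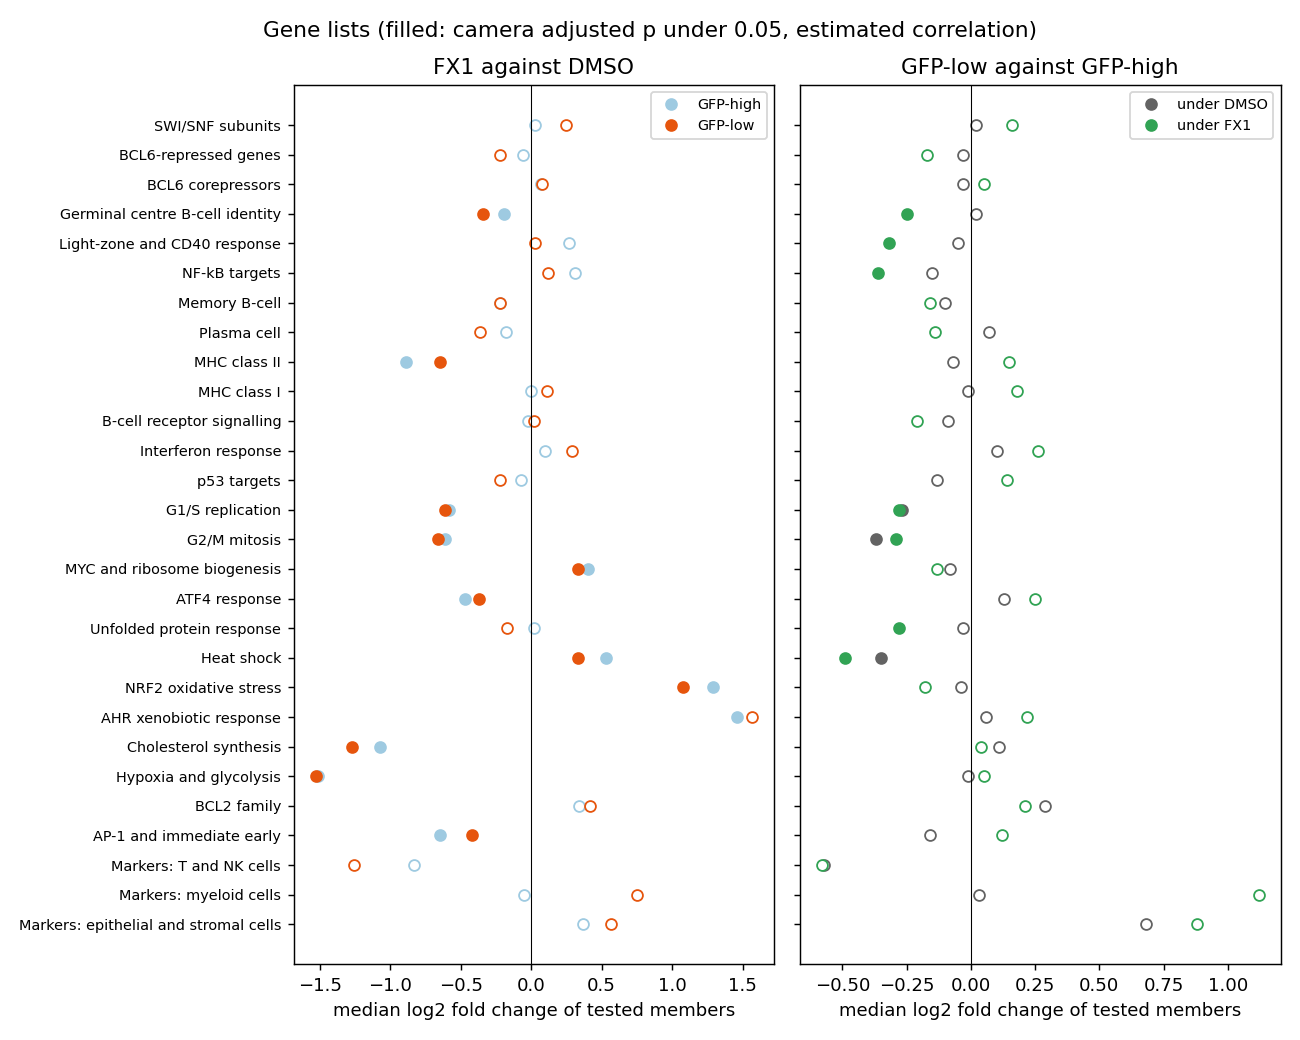
Median log2 fold change of the tested members of each of the 28 gene lists, for FX1 against DMSO in both GFP gates and for GFP-low against GFP-high under both treatments, filled where the camera adjusted p with an estimated correlation passed 0.05. NRF2 genes lie at 1.29 and 1.08 and cholesterol synthesis genes at -1.07 and -1.27 with FX1, and NF-kB targets at -0.36 in GFP-low under FX1.

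The comparison of GFP-low with GFP-high cells under DMSO addressed the difference between the gates without FX1. It cannot separate the gate from a difference between cultures or library preparations that coincides with the groups. Heat shock genes fell in 9 of 11 cases and rose in 1 (median -0.35, camera adjusted p = 1.4e-14), with HSP90AA1 at -0.56 ± 0.011. G2/M genes fell in 21 of 24 and rose in 2 (median -0.37, camera adjusted p = 3.7e-22), with TOP2A at -0.53 ± 0.015, as did G1/S genes in 18 of 23 (median -0.27, camera adjusted p = 6.3e-12), with PCNA at -0.7 ± 0.021. PRDM1 rose by 0.97 ± 0.048, whereas BCL6 fell by 0.24 on the log2 scale. The heat shock, G2/M and G1/S calls held with an estimated correlation, the largest adjusted p being 0.0059. NF-kB targets fell in 13 of 22 cases and rose in 5 (camera adjusted p = 0.019, adjusted p = 0.076 with an estimated correlation), with lymphotoxin genes LTB at -1.33 ± 0.045 and LTA at -0.65 ± 0.034. With the GC and length trend removed, the camera adjusted p of the NF-kB list was 4.1e-06 at the preset correlation. CD83 fell by 0.57 and SLAMF1 by 0.44 on the log2 scale.

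Several further list calls under DMSO were lost with an estimated correlation. MYC and ribosome biogenesis fell in 11 of 22 cases and rose in 7 (camera adjusted p = 0.011, adjusted p = 0.059 with an estimated correlation), with nucleolin NCL at -0.52 ± 0.012. The ATF4 list rose in 12 of 20 and fell in 3 (median 0.13, camera adjusted p = 0.019, adjusted p = 0.091 with an estimated correlation), with a median of 0.06 and adjusted p = 0.15 with the GC and length trend removed. The B-cell receptor list fell in 11 of 21 and rose in 5 (camera adjusted p = 0.024, adjusted p = 0.21 with an estimated correlation) and AP-1 and immediate early genes fell in 9 of 19 and rose in 1 (camera adjusted p = 0.03, adjusted p = 0.14 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 19 cases and fell in 6 (camera adjusted p = 0.04, adjusted p = 0.11 with an estimated correlation), with MVD at 0.73 ± 0.027, DHCR7 at 0.44 ± 0.02 and SQLE at -0.42 ± 0.016. Removing the trend at the preset correlation gave camera adjusted p = 5.2e-06 for MYC and ribosome biogenesis and 2.2e-06 for the B-cell receptor list. For AP-1 and immediate early genes it gave 4.4e-06, and for cholesterol synthesis 0.0081. Adjusted over the list alone, 12 B-cell receptor genes fell and 6 rose, and the other lists of this comparison named above kept their counts. Among markers of other cell types, the myeloid marker ITGAM rose from 0.868 to 1.91 CPM (1.15 ± 0.23) and the stromal marker COL1A1 from 9.03 to 12.5 CPM (0.48 ± 0.086). Of 6 T and NK cell markers 3 fell, or 4 adjusted over the list alone, with LCK at -0.58 ± 0.087. Camera adjusted p was 0.71 for myeloid, 0.48 for epithelial and stromal, and 0.54 for T and NK cell markers.

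By edgeR, 8233 genes differed between the gates under DMSO, 3876 higher and 4357 lower in GFP-low, but only 374 and 216 by at least 2-fold, and 199 passed the 1.5-fold floor, 75 higher and 124 lower. Protein-coding genes made up only 113 and 55 of the 2-fold calls. More genes had an estimated fold of 2 or more than passed the 1.5-fold floor, so many of those folds were imprecise. The largest rises were in ADAMTS13 (1.22 ± 0.14), MCRIP1 (1.07 ± 0.094), NME3 (1.02 ± 0.092), TMCC2, MRPL12, MAP2K6, CCDC102A, LMF1, ALDH4A1 and PRDM1. The largest falls were in RNY1 (-3.63 ± 0.14), RNVU1-31, SCARNA5, the signalling adaptor gene SH2D1A (-1.52 ± 0.064), the histone genes H4C11 and H4C12 (-1.45 ± 0.055 and -1.38 ± 0.056), LTB, TMPRSS3, FABP5 and DNAH12. The 10 largest rises had a median transcript GC content of 62.2% against 50% for the 10 largest falls, and the change followed GC content across genes (rho 0.515). With the trend removed, 5749 of 8183 calls kept direction and significance, 2327 were lost and 107 turned.

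The comparison of GFP-low with GFP-high cells under FX1 addressed the gate in inhibitor-treated cells. NF-kB targets fell in 15 of 22 cases and rose in 3 (median -0.36, camera adjusted p = 2.5e-11, adjusted p = 0.0029 with an estimated correlation), with LTA at -1.61 ± 0.032, CCL3 at -1.82 ± 0.043, LTB at -1.25 ± 0.04 and the apoptosis inhibitor BIRC3 at -0.5 ± 0.013. Light-zone and CD40 genes fell in 14 of 20 cases and rose in 4 (median -0.32, camera adjusted p = 6.3e-06, adjusted p = 0.0063 with an estimated correlation), with CD83 at -1.12 ± 0.016 and SLAMF1 at -1.1 ± 0.031. The light-zone and NF-kB lists share members, so these results are not independent. Heat shock genes fell in 9 of 11 cases and rose in 1 (median -0.49, camera adjusted p = 1.1e-15) and G2/M genes in 20 of 24 (median -0.29, camera adjusted p = 2.5e-11). G1/S genes fell in 18 of 23 and rose in 2 (median -0.28, camera adjusted p = 2.2e-05), and unfolded protein response genes fell in 12 of 16 and rose in 2 (median -0.28, camera adjusted p = 5e-05), with HSPA5 at -0.34 ± 0.013. These calls held with an estimated correlation, the largest adjusted p being 0.016. PRDM1 was higher by 0.63 ± 0.03 and the antibody joining chain gene JCHAIN changed by -1.07 ± 0.014.

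Germinal centre identity genes fell in 14 of 24 cases and rose in 8 (camera adjusted p = 0.0018, adjusted p = 0.019 with an estimated correlation), with RGS13 at -1.24 ± 0.023, SERPINA9 at -0.85 ± 0.02 and CXCR4 at 0.83 ± 0.027. BCL6-repressed genes fell in 15 of 22 and rose in 5 (camera adjusted p = 0.01, adjusted p = 0.061 with an estimated correlation), with CD69 at -1.38 ± 0.048 and MIR155HG at -1.25 ± 0.053. NRF2 genes fell in 9 of 13 and rose in 3 (camera adjusted p = 0.0016, adjusted p = 0.084 with an estimated correlation), NQO1 by 0.54 on the log2 scale, and the B-cell receptor list fell in 13 of 21 and rose in 6 (camera adjusted p = 0.011, adjusted p = 0.12 with an estimated correlation). Of 4 myeloid markers 3 rose (median 1.12, camera adjusted p = 0.3), ITGAM going from 1.74 to 5.05 CPM (1.54 ± 0.16), while CD14 and CD68 stayed under 1 CPM and were not called with the GC and length trend removed. COL1A1, 1 of 2 epithelial and stromal markers, rose from 8.44 to 16.3 CPM (0.96 ± 0.078, camera adjusted p = 0.21 for the list). Of 6 T and NK cell markers 4 fell (median -0.58, camera adjusted p = 0.6), with CD3D at -0.86 ± 0.21. Adjusted over the list alone, counts matched those over all genes for the lists named in this comparison.

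By edgeR, 10158 genes differed under FX1, 5391 higher and 4767 lower in GFP-low, 672 and 216 by at least 2-fold, and 728 passed the 1.5-fold floor, 362 higher and 366 lower. Protein-coding genes made up 315 and 103 of the 2-fold calls. Which direction held more calls depended on the setting. There were 4775 higher and 5280 lower without mitochondrial and dominant genes, 4896 and 5239 with only the groups compared, 4649 and 4892 by DESeq2, and 3725 and 4800 with the GC and length trend removed. Without GFP-high DMSO replicate 1, 2 or 3 there were 4778 and 5342, 4741 and 5351, and 4784 and 5341. The median log2 change over all genes was then 0.04, 0.037 and 0.039, against 0.079 in the main fit. The largest rises included DERL3 (1.56 ± 0.089), MAP1A (1.48 ± 0.095), CALHM1, RINL, KCNH2, LRRC56, ABCA7 (1.2 ± 0.033), KCNN4 and ADAMTS13. These 9 had a median transcript GC content of 62.9%, against 49.2% for the 10 largest falls. With the GC and length trend removed all 9 stayed called but were smaller, from 1.24 for DERL3 to 0.72 for ABCA7. The largest falls were in RNY1 (-4.01 ± 0.36), the chemokine gene CCL4 (-2.25 ± 0.089), H4C11, CCL3, B3GNT5, H4C12, LTA, CCL4L2, SH2D1A and H2BC18. RNY1, a short noncoding RNA, went from 5.4 ± 0.22 to 0.287 ± 0.18 CPM (SD), so its fall rests on a value near the floor. The GFP-low effects under the 2 treatments, which share no library, had r = 0.453 and rho = 0.535 across genes, and 5965 of 6459 genes called in both (92.4%) had the same direction. In this comparison the change followed GC content with rho 0.685, and with the trend removed 6232 of 10066 calls kept direction and significance, 3072 were lost and 762 turned. By at least 2-fold, 394 genes were then higher and 197 lower, against 672 and 216. SMARCA4 RNA, higher by 0.23 ± 0.015, was at -0.15 without the trend.

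**Figure D3:**
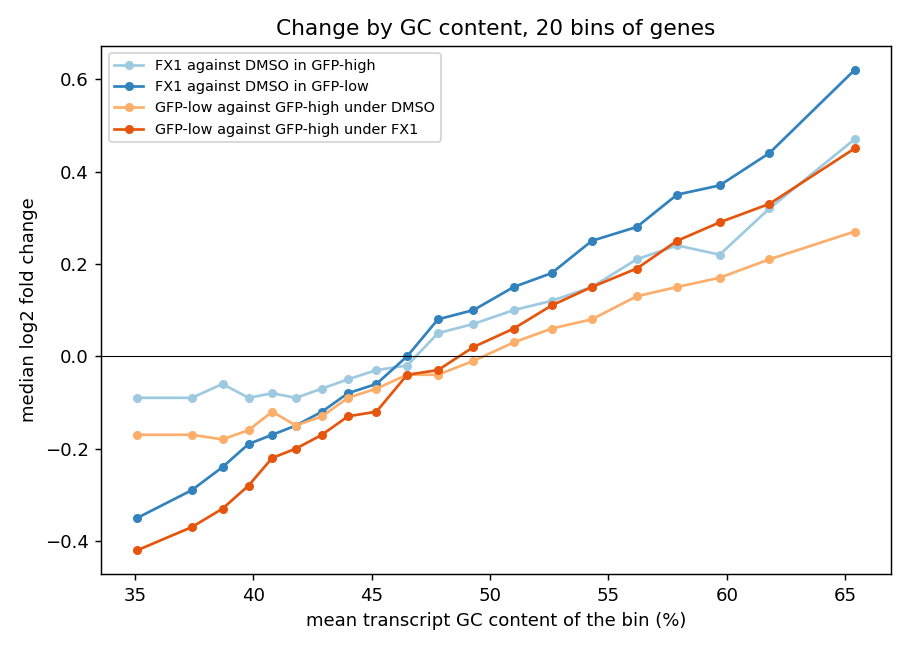
Median log2 fold change in 20 bins of 521 or 522 genes by mean transcript GC content in percent, a line for each of the 4 pairwise comparisons. GFP-low against GFP-high under FX1 runs from -0.42 in the bin at 35.1% GC to 0.45 in the bin at 65.4%.

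The test of the difference of the FX1 effect between the gates asked whether the response differed between them. Among its 10 largest falls were CCL3 at -1.47 ± 0.08 (log2), CCL4 at -1.36 ± 0.18, CCL4L2 at -1.34 ± 0.08 and CCL3L3 at -1.09 ± 0.042, which rose less with FX1 in GFP-low cells. CCL3 with CCL3L3, and CCL4 with CCL4L2, are near-identical copies that may share reads, so they are not separate observations. No list of chemokine genes was tested, and CCL22 fell in both gates, by 2.51 in GFP-high and 2.58 in GFP-low cells on the log2 scale. NF-kB targets were lower in this difference in 11 of 22 cases and higher in 1 (camera adjusted p = 1.1e-07, adjusted p = 0.0049 with an estimated correlation). Light-zone genes, some of which are also on the NF-kB list, were lower in 10 of 20 against 4 (camera adjusted p = 7.1e-05, adjusted p = 0.0099 with an estimated correlation). Germinal centre identity genes were lower in 15 of 24 against 4 (camera adjusted p = 1.3e-06, adjusted p = 0.0049 with an estimated correlation), led by RGS13 at -0.81 ± 0.029. AP-1 and immediate early genes went the other way in 11 of 19 cases against 1 (camera adjusted p = 5.2e-05, adjusted p = 0.019 with an estimated correlation). FOSB differed by 1.39 ± 0.083 and FOS by 1.23 ± 0.12, both having fallen less in GFP-low cells, which does not hold for every member.

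BCL6-repressed genes were lower in the difference in 13 of 22 cases and higher in 3 (camera adjusted p = 0.00043, adjusted p = 0.021 with an estimated correlation), CD69 by -1.09 ± 0.066 and MIR155HG by -1.24 ± 0.08. MHC class II genes fell less in GFP-low, 8 of 13 being higher in the difference and 1 lower (camera adjusted p = 0.00012, adjusted p = 0.012 with an estimated correlation), with CD74 at 0.25 ± 0.015. BCL6 itself differed by 0.36 ± 0.025 and PRDM1 by -0.34 ± 0.057. NEAT1, an abundant nuclear noncoding RNA, went from 1440 to 982 CPM with FX1 in GFP-high cells and from 953 to 1330 in GFP-low cells, a difference of 1.03 ± 0.017, whereas LYPLA1 and TMED7 differed by -1.06 ± 0.025 and -1.11 ± 0.049. Adjusted over the list alone, 2 NF-kB targets, 5 light-zone genes, 11 MHC class II genes and 12 AP-1 genes were higher, and the other counts of the lists named in this comparison were equal to those over all genes.

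By edgeR, 5583 genes differed in their FX1 effect, 2636 upward and 2947 downward, 280 and 147 by at least 2-fold, and 151 passed the 1.5-fold floor, 66 upward and 85 downward. Protein-coding genes made up 89 and 39 of the 2-fold calls. With mitochondrial and dominant genes left out before scaling, the split of all calls was 2014 upward and 3617 downward. Of the 5583, 1773 changed in the same direction in both gates and more in GFP-low, 1412 in the same direction and less, 575 in opposite directions, and 1823 passed the test in 1 gate or neither. The average FX1 effect and the average GFP-low effect, which are orthogonal, had r = 0.218 and rho = 0.282 across genes. Differences here followed GC content with rho 0.459, and with the trend removed 3735 of 5552 calls kept direction and significance, 1768 were lost and 49 turned.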

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

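Chosen only after the results were seen were the tests on the NF-kB, cholesterol synthesis and NRF2 lists, the test of GC content shared within groups, and the removal of a GC and length trend. For the counts over other splits and the comparison of GC trends within groups, the possible outcomes were written down before those tests. No test of GC content was among the tests set before the data were examined.

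The FX1 effect differed between GFP-low and GFP-high cells, by the test of the difference itself, for 5583 genes. Higher in this difference were RNVU1-31 (1.48), FOSB (1.39), SCARNA5 (1.24), FOS (1.23), MAP1A (1.17), NEAT1 (1.03), TTC34 (0.98), UPP1 (0.96), SLC27A3 (0.96) and MICA (0.94). Lower were CCL3 (-1.47), CCL4 (-1.36), CCL4L2 (-1.34), CLIC2 (-1.23), PCLAF (-1.16), TMED7 (-1.11), CD69 (-1.09), CCL3L3 (-1.09), LYPLA1 (-1.06) and MS4A7 (-1.03). Reads of CCL3 and CCL3L3, and of CCL4 and CCL4L2, may be shared. BCL6 differed by 0.36, PRDM1 by -0.34 and SMARCA4 by 0.18, all on the log2 scale. With the GC and length trend removed, SMARCA4 was at 0 (edgeR adjusted p = 0.98), its fold and its call both lost, while BCL6 was at 0.3 and PRDM1 at -0.37.

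The gene lists whose FX1 effect differed by camera had these median log2 differences. AP-1 and immediate early genes had 0.31, MHC class II 0.17, MHC class I 0.13 and SWI/SNF subunits 0.12. Germinal centre identity had -0.28, NF-kB targets -0.26, heat shock -0.21, light-zone genes -0.19, plasma cell genes -0.18, the unfolded protein response -0.17, BCL6-repressed genes -0.16, NRF2 genes -0.15 and cholesterol synthesis -0.09. For SWI/SNF subunits the camera adjusted p was 0.027 (adjusted p = 0.054 with an estimated correlation, and 0.33 with the GC and length trend removed) and for plasma cell genes 0.0071 (adjusted p = 0.091 with an estimated correlation). For MHC class I it was 0.0071 (adjusted p = 0.037 with an estimated correlation, and 0.4 with the trend removed). With that trend removed the medians were 0.02 for SWI/SNF subunits, 0.01 for MHC class I, 0.1 for MHC class II, -0.17 for NF-kB targets, -0.14 for heat shock, -0.24 for NRF2 genes and 0.21 for AP-1 and immediate early genes, the last 5 still called by camera.

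Of 50 splits of the 12 libraries for the difference of the FX1 effect, 1 called as many genes, the real one with 5583, and the highest of the others called 198. Whether chance can be excluded stays open, because the other splits mix the 4 groups, whose differences then enter the spread and lower the calls with or without a true difference of the FX1 effect. For the 4 pairwise comparisons, the 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 split called as many genes as the real one, itself. The real counts were 12224, 12138, 8233 and 10158 and the highest of the other splits 0, 0, 0 and 1, for FX1 in GFP-high, FX1 in GFP-low, GFP-low under DMSO and GFP-low under FX1.

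NF-kB target RNA was lower in GFP-low than in GFP-high cells under FX1, with a median log2 change of -0.36. With the GC and length trend removed the median was -0.46 (camera adjusted p = 1.5e-29), and without mitochondrial and dominant genes it was -0.4, which argues against either as the whole cause. The 20 of 22 members with no near-identical copy had a median of -0.28, which argues against reads shared between paralogs as the whole cause. A lower NF-kB response in the GFP-low gate is a candidate explanation, found and tested on the same data, and the labels do not tie the gate to a level of SMARCA4 protein. A difference between cultures or library preparations that coincides with the groups was not tested.

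Changes in GFP-low cells against GFP-high cells followed GC content in sign, upward in GC-rich and downward in GC-poor genes. The mean slope of log2 level on GC content, per 10 percentage points, was -0.188 in GFP-high DMSO, -0.0285 in GFP-high FX1, -0.0361 in GFP-low DMSO and 0.252 in GFP-low FX1, and the largest difference within a group was 11.1% of the smaller difference between the gates, which argues against a bias of single libraries. The GFP-low effect under FX1 followed GC content with rho 0.685, and a GC bias shared by the libraries of a group cannot be told apart from an effect of the gate, because each group's libraries may have been prepared together. Small changes of GC-rich or GC-poor genes therefore stay open in direction.

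Cholesterol synthesis RNA was lower and NRF2 target RNA higher with FX1, with medians of -1.07 and 1.29 in GFP-high cells. With the GC and length trend removed, the medians were -0.97 and 1.37, and without mitochondrial and dominant genes -1.07 and 1.3, which argues against both as the whole cause. In GFP-low cells the medians of -1.27 and 1.08 became -1.21 and 1 with the trend removed, and -1.31 and 1.04 without those genes. A response of these pathways to FX1 is a candidate explanation, as a hypothesis, and whether it passes through BCL6 was not tested, since no other inhibitor or dose is in the series.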

How the results depend on the processing

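The 1.5-fold floor, the removal of a GC and length trend and the summed replicates were chosen only after the results were seen. Counts of called genes in the 5 comparisons stayed within 1.5 times under every setting run on them except the 1.5-fold floor, which left 3674 genes for FX1 in GFP-high, 3606 for FX1 in GFP-low, 199 for GFP-low under DMSO, 728 for GFP-low under FX1 and 151 for the difference of the FX1 effect, because it tests for larger changes. Leaving out each library gave 11475 to 12379, 11440 to 12293, 7451 to 8275, 9387 to 10205 and 5167 to 5432 genes, and 12 to 14, 14 to 17, 7 to 9, 10 to 11 and 12 to 13 lists. With an estimated correlation, 3 lists passed for GFP-low under DMSO, against 9. Removing the GC and length trend added 11 list calls over the 5 comparisons and lost 6, the other 123 list tests keeping their outcome. The upward calls of the difference, 2636 of 5583, were 1797, 1759 and 1863 without GFP-high DMSO replicates 1, 2 and 3. The median log2 difference over all genes, 0.024 in the main fit, was then -0.028, -0.027 and -0.025. Leaving out mitochondrial and dominant genes before scaling gave a median of -0.02 and 2014 upward calls. The split thus went with a small shift of the median over all genes, which depends on library scaling. What moved the scaling was not tested. With the GC and length trend removed, FX1 calls were 6495 upward and 5538 downward in GFP-high cells and 6246 and 5302 in GFP-low cells, and with at least 50 counts in 3 libraries the difference had 2983 upward and 2622 downward. The near-even FX1 splits also turned without the count filter, to 6161 upward and 6056 downward in GFP-high and 6175 and 5993 in GFP-low cells, and without some single replicates.

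The correlations across genes were 0.829 (FX1 effects), 0.453 (GFP-low effects) and 0.218 (average effects). They were 0.889, 0.631 and 0.271 with at least 50 counts in 3 libraries, where fewer, higher genes enter, and 0.834, 0.406 and 0.175 with the GC and length trend removed. Leaving out a library gave 0.803 to 0.812, 0.405 to 0.429 and 0.177 to 0.255. More genes then passed the count filter, 18185 to 18438 against 17859. The gene set thus changed along with the library left out, and these were not tested apart.

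Among the genes reported singly, directions reversed only with the GC and length trend removed, which acts on GC-rich and GC-poor genes by its construction. With FX1 in GFP-high cells, SMARCA4 was then at -0.23, and in GFP-low cells SMARCA4 was at -0.23 and COL1A1 at -0.05. For GFP-low under DMSO, SMARCA2 was at 0.02, SMARCA4 at -0.15, CTBP1 at -0.04 and CIITA at -0.03. For GFP-low under FX1, SMARCA4 was at -0.15, ARID1A at -0.1, ARID1B at -0.04, CTBP1 at -0.22, HDAC3 at -0.03, SKI at -0.15, CIITA at -0.04, HLA-B at -0.13, SLC7A5 at -0.13, BCL2L1 at -0.02, JUNB at -0.16 and IER2 at -0.05, and for the difference ARID1A was at -0.01.

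Same-numbered libraries did not deviate together (correlations -0.037 to 0.018, against -0.031 to 0.035 for other numbers). The variance within groups was only 1.66 to 1.9 times that of random sampling of reads. Paired libraries could therefore also show no shared deviation, and whether the numbers pair them stays open. With the replicate number as a block, 12184, 12101, 8213, 10111 and 5536 genes were called. With replicates summed to 4 libraries and 1 residual degree of freedom, which takes the difference of the FX1 effect as noise, 8513 genes were called for the average FX1 effect against 13543 with the 12 libraries, and 2936 against 10862 for the average GFP-low effect.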

Other observations

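With FX1 in GFP-high cells, the plasma cell list had 6 risers and 7 fallers of 14 (camera adjusted p = 0.59), with SLAMF7 at 1.63 ± 0.055 and the secretory pathway gene DERL3 at -1.67 ± 0.091. Memory B-cell genes rose in 2 and fell in 7 of 11 cases (camera adjusted p = 0.74), with GPR183 at -0.56 ± 0.07. Interferon response genes rose in 9 and fell in 1 of 18 (camera adjusted p = 0.44), including IFIT2 at 1.45 ± 0.16. In the BCL2 family 9 of 15 rose and 5 fell (camera adjusted p = 0.65), the anti-apoptotic gene MCL1 at -0.63 ± 0.016 and the pro-apoptotic gene PMAIP1 at 0.56 ± 0.03. MHC class I genes split 6 and 6 (camera adjusted p = 0.51), with the peptide transporter gene TAP2 at 0.88 ± 0.026 and HLA-E at -0.71 ± 0.024. Unfolded protein response genes rose in 7 and fell in 6 of 16 (camera adjusted p = 0.89), with PDIA6 at -0.57 ± 0.016. Of SWI/SNF subunits 13 of 27 rose and 6 fell (camera adjusted p = 0.35), with ARID1B at 0.46 ± 0.016 and BRD7 at -0.45 ± 0.025, and of BCL6 corepressors 5 of 9 rose and 2 fell (camera adjusted p = 0.65), with TBL1XR1 at -0.31 ± 0.014. AHR response genes rose in 3 of 4 cases (camera adjusted p = 6.3e-05, adjusted p = 0.0075 with an estimated correlation), NQO1 being on the NRF2 list too and AHRR and CYP1A1 lying under 1 CPM in both GFP-high groups.

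Of 6 tested T and NK cell markers, 5 fell with FX1 in GFP-high cells (camera adjusted p = 0.29), LCK going from 16 to 4.08 CPM and CD3D from 3.33 to 1.87. Of 4 myeloid markers 1 rose and 1 fell (camera adjusted p = 1), with ITGAM at 0.868 and 1.74 CPM. Of 2 epithelial and stromal markers 0 were called (camera adjusted p = 1), with COL1A1 at 9.03 and 8.44 CPM.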
